A study of Bacillus velezensis with 12 samples.

How the data were processed

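RNA of Bacillus velezensis was sequenced from axenic cultures and from cocultures with Colletotrichum gloeosporioides at 8 h and 13 h, with 3 libraries per group and 12 in all. Per the labels' protocols, cultures grew in a stirred bioreactor in potato dextrose mineral medium, ribosomal RNA was removed before sequencing, and samples were taken before glucose ran out. Groups were taken from the labels. The strain's genome and annotation were not given in the sources used here, so positions are the numbers at the end of the gene identifiers, and neighbours are consecutive numbers.

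The deposited count table holds expected counts per coding sequence, made by the authors with Salmon 0.14.1 per the submitters' processing notes, not scaled to depth or length. It has 3846 coding sequences, and 4 to 9 values per library that are not whole numbers. Counts were rounded, which moved no value by more than 0.49. Library totals ran from 1013316 to 2230202 counts, and the report gives all of them. The authors' deposited lists of changed genes give log2 fold changes and mean log2 CPM per the file headers. They also give the authors' p-values and false discovery rates per the file headers, and the test behind them is not given in the sources used here. The false discovery rates divided by p-values and multiplied by ranks give a median of 3542 genes tested. The list for the interaction with the fungus holds 461 genes and the list for time 1225, of which 1 has no identifier, and 88 genes are in both. By their values the lists give coculture against axenic averaged over times, and 13 h against 8 h averaged over cultures. The descriptions of 1597 coding sequences come from these lists, 177 of them hypothetical proteins, and 2249 have none.

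All 12 libraries were fitted together with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with robust dispersion, a mean per group, TMM scaling and the filterByExpr filter, which kept 3197 coding sequences, 1549 of them described. The common biological coefficient of variation was 0.377 with 8 residual degrees of freedom. The 7 comparisons were coculture against axenic culture at 8 h, at 13 h and averaged, 13 h against 8 h in axenic culture, in coculture and averaged, and the difference of the coculture effects between times, which is also the difference of the time effects between cultures. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at adjusted p under 0.05. Errors of log2 fold changes (SE) are approximate. Each is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM are means with SD over 3 libraries on the TMM scale.

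Gene lists were fixed as words matched to descriptions, 38 in number. The 26 lists with 3 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 against the described genes alone, adjusted over lists. The test was repeated with the correlation estimated from the data, and with fry. The genes named follow a rule set before the data were examined. It takes the 8 largest rises and falls per coculture comparison, 6 per time comparison and 5 for the difference of effects. Such genes passed, had a mean log2 CPM of 3 or more and a description, and, except for the difference of effects, had no overlap between the libraries compared. It adds up to 3 members of each list per comparison, and regulators, of which SigB and SigF had a description. "Largest" therefore covers these genes alone. The chitin-binding protein at 13 h and the metal transport genes of the closing section were added after their values were seen. So were the genes of the closing section that rose 16-fold or more at both times and were not named by the rule. The comparisons, lists, threshold and most alternatives were also set before the data were examined. Agreement of libraries within a group was measured by chi-square per degree of freedom over genes with 10 or more counts in the pair. Where a group held 1 to 3 counts of a gene in all, the ratio of normalised counts is given with an exact binomial 95% interval.

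Alternatives were RLE size factors, upper-quartile scaling, no low-count filter (3812 coding sequences), a filter of 10 CPM in 3 libraries (3068), DESeq2 1.42.0, limma-voom, only the groups compared, a replicate block, adjusted p under 0.01, a fold change threshold beside adjusted p, thinning of all libraries to the smallest total, and each library left out. After the data were seen, no composition scaling, summing of near-identical libraries, leaving out the first library of every group, and lists trimmed of members that matched by text alone were added. The analysis was tested on simulated data of 3197 genes with 200 changed. At 4-fold change it recovered 72.7% (coculture at 8 h), 68.8% (coculture at 13 h), 95.9% (coculture averaged), 76% (time in axenic culture), 57.6% (time in coculture), 98% (time averaged) and 16.2% (difference of effects) of changed genes. At 2-fold change it recovered 2%, 10%, 44.3%, 15.2%, 4.1%, 45.5% and 0%, and 3.5% to 6.3% of calls were false. Simulated libraries were drawn independently, without near-identical pairs, so these shares may not hold for the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the tables and figures. Stable RNA was not in the table, so no count could be scaled to it.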

Results

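Transcripts of Bacillus velezensis, a Gram-positive soil bacterium used against plant disease, were counted by RNA sequencing in 2 kinds of culture. The bacterium grew alone (axenic) or with Colletotrichum gloeosporioides, a fungus that causes anthracnose on fruit. Each kind was sampled at 8 h and 13 h, with 3 libraries per group that the labels call biological replicates, so 12 libraries in all. The comparisons address how gene expression of the bacterium differed in the presence of the fungus, how it differed between the sampling times, and whether the first difference depended on the time. Axenic libraries at 8 h held 1043447, 1788067 and 1013316 counts, and those at 13 h held 1205709, 1626413 and 1922099. Coculture libraries held 1971087, 1359136 and 1505991 counts at 8 h, and 2230202, 1345834 and 1217014 at 13 h. The table covered 3846 coding sequences (CDS), with a median count per CDS of 30 to 107 across libraries. Of these, 1597 (41.5%) carry a product description, each from the authors' deposited lists of changed genes. Genes are therefore named below by product and CDS number, and members of gene lists come only from genes the authors selected on these samples, so a list's direction is not independent evidence.

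The groups separated from each other. On log2 CPM, the first principal component held 53.4% of the variance and ran from the 8 h to the axenic 13 h libraries, and the second held 25.1% and parted axenic from coculture libraries. Replicates 2 and 3 were very close in 3 groups. Their chi-square per degree of freedom was 2.25 in axenic culture at 8 h, 2.48 in axenic culture at 13 h and 1.78 in coculture at 13 h, against 39.2 to 124 for pairs with replicate 1 of those groups. In coculture at 8 h replicates 2 and 3 gave 23.5, and their pairs with replicate 1 gave 99.5 and 111. Counting noise alone gives a value near 1. The libraries were kept separate because the labels call them biological replicates, and these values do not tell whether a close pair came from separate cultures. The total of changed genes in each comparison is also given with every close pair summed to a single library, and so are the counts of many, but not all, named lists.

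**Figure D1:**
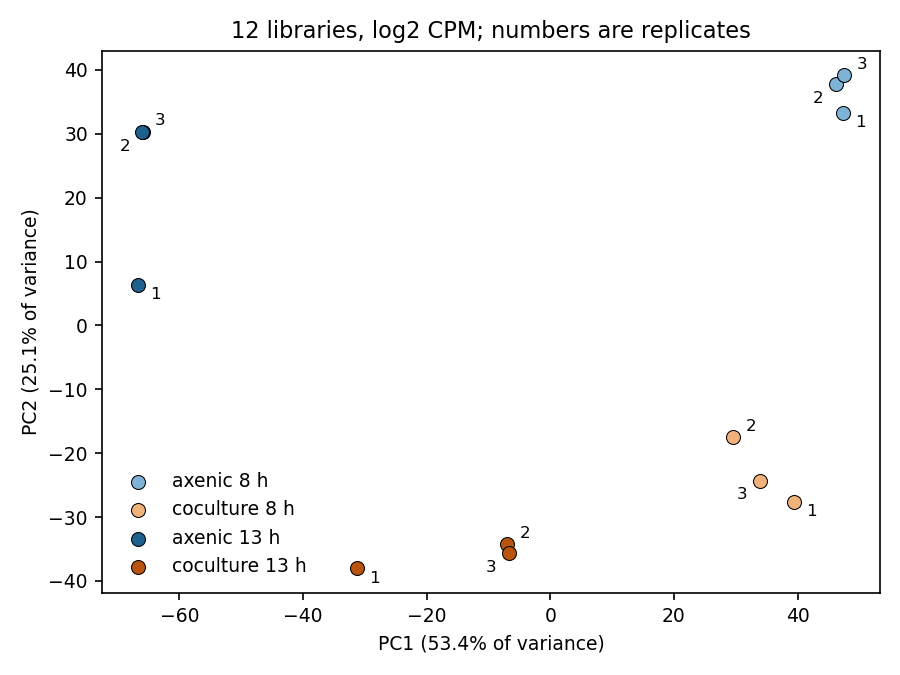
Principal components 1 (x axis, 53.4% of variance) and 2 (y axis, 25.1%) of log2 CPM for the 12 libraries, coloured by group and numbered by replicate. Replicates 2 and 3 lie almost on each other in axenic culture at 13 h and in coculture at 13 h, and axenic and coculture libraries are farther apart at 13 h than at 8 h along component 1.

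At 8 h a run of adjacent genes was among the largest rises in coculture. The gene described as glutathione-dependent formaldehyde dehydrogenase (CDS 302), whose function was not tested, rose from 12.6 ± 13.8 to 4379 ± 1238 CPM (mean ± SD, n = 3). Its log2 fold change was 8.45 (SE 0.93, adjusted p = 0.000141). Its neighbours, a GTP-binding protein (CDS 301) and an RDD family protein (CDS 303), rose by 7.64 and 6.18 on the log2 scale. A 30S ribosomal protein S14 gene (CDS 838) held 2 counts in all axenic 8 h libraries together and 758 in coculture, a ratio of 268.1 with a 95% counting interval of 74.0 to 2217.6 (such intervals cover counting error alone). The type B form of 50S ribosomal protein L31 (CDS 2803) rose by 5.45 (SE 0.72), from 48.0 ± 55.7 to 2081 ± 479 CPM. Among the largest falls were the ribulose monophosphate enzymes 3-hexulose-6-phosphate synthase (CDS 309) and 6-phospho-3-hexuloisomerase (CDS 308), which fix formaldehyde into sugar phosphates. The synthase went from 1636 ± 397 to 11.6 ± 1.34 CPM (log2 fold change -7.13, SE 0.45, adjusted p = 3.21e-06), and the isomerase had a log2 fold change of -6.53 (SE 0.43).

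General stress genes rose together at 8 h. Of 10 tested members of the SigB list, 8 rose, none fell and 2 did not pass, and 9 rose when adjusted over the list alone. SigB itself (CDS 450), the sigma factor of the general stress regulon, rose by 3.03 (SE 0.27, adjusted p = 2.61e-05), from 387 ± 48.9 to 3165 ± 564 CPM. General stress proteins CDS 705 and CDS 387 rose by 5.51 and 5.03, and a lipid kinase of the BmrU family (CDS 2235), which matched the list by its description, by 4.56. The list ranked above other described genes (camera adjusted p = 1.31e-06), but adjusted p = 0.877 with an estimated correlation. A stress response membrane protein of the GlsB family (CDS 3563), outside that list, rose by 7.28 (SE 1.23) from an axenic level of 1.31 ± 1.14 CPM, and a D-lyxose/D-mannose isomerase (CDS 385) by 5.66 from 1.99 ± 1.34 CPM. Of 5 oxidative stress genes 4 rose, among them catalases CDS 3640 (5.33, SE 0.63) and CDS 831 (3.16, SE 0.79), and the list test did not pass (adjusted p = 0.119). The phage-shock type protein PspA/IM30 (CDS 3041), which binds damaged membranes, rose by 3.60.

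Genes for a polymer, 1 surfactin gene and some nitrogen genes fell at 8 h, while neither nitrogen list passed its test. Both poly-gamma-glutamate genes fell. The synthase PgsB (CDS 3320) had a log2 fold change of -5.44 (SE 1.29), PgsC (CDS 3319) was 83.4 times lower with a counting interval of 22.6 to 696.8, and the adjacent capsular polysaccharide gene (CDS 3318) had -5.63 (SE 1.33). The ammonium transporter (CDS 3390) had -5.42 (SE 0.81), the nitrate transporter of the NarK/NasA family (CDS 300) -4.42 and nitrite reductase (CDS 298) -3.25. Within the nitrogen limitation list 1 of 11 members rose and 3 fell, and within the anaerobic and nitrate list 1 of 9 rose and 2 fell. These list tests gave adjusted p = 0.296 and 0.731. The nitrogen limitation list took in PgsB and other members by text alone, and held 6 without them. After summing the close pairs PgsC passed and PgsB did not, and each of these 2 lists held 2 falling genes and none that rose. The surfactin thioesterase SrfAD (CDS 314) had -3.06 (SE 0.68), a fatty acid desaturase (CDS 3721) -4.64 and a VWA domain protein (CDS 3413) -4.44. All 4 pyrimidine synthesis genes fell, such as dihydroorotase (CDS 1501, -4.26) and orotate phosphoribosyltransferase (CDS 1507, -3.95). Their list had adjusted p = 0.0301, and adjusted p = 0.967 with an estimated correlation. None of these 4 passed with the close pairs summed.

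Ribosomal protein genes went both ways at 8 h. Of 49, 10 fell, 3 rose and 36 did not pass (26 fell and 4 rose when adjusted over the list alone). After summing the close pairs none fell and 3 rose. The risers were S14 (CDS 838), type B L31 (CDS 2803) and a 50S L33 gene (CDS 2219, 3.74, SE 0.69), while the median log2 fold change of the list was -1.0. The list was shifted down (adjusted p = 0.000601), with adjusted p = 0.967 with an estimated correlation and adjusted p = 0.154 with fry. Of 26 genes matched to respiration and ATP synthase, 9 rose and none fell (adjusted p = 0.294). Among them were cytochrome bd oxidase genes, which serve respiration at low oxygen: CDS 3625 rose by 4.87 (SE 0.88) and CDS 2805 by 3.81 (SE 0.70), and CDS 2804 was 35.7 times higher with a counting interval of 9.6 to 299.0. L-lactate dehydrogenase (CDS 275) rose by 3.32. Argininosuccinate synthase and lyase (CDS 2671 and CDS 2670) rose by 4.11 (SE 1.27) and 4.08 (SE 1.17), calls that ended when any of the axenic 8 h libraries was left out. Of 10 motility and chemotaxis genes 5 rose and 2 fell, for example chemotaxis protein CDS 694 (2.27) and the hook-associated protein FlgK (CDS 3272, 1.63), without a shift of the list (adjusted p = 0.315). A DinB family protein (CDS 2822), which the SOS list took in by text alone, rose by 2.21, and 5 of that list's 13 members rose (adjusted p = 0.293). After that summing 4 respiration genes, 1 oxidative stress gene, 1 SOS gene, 7 SigB list genes and no motility or arginine gene passed.

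In all, 619 of 3197 tested CDS passed at 8 h, 381 higher and 238 lower in coculture. Of the 1549 described genes tested 397 passed in either direction, and the list counts at 8 h are to be read against that share. With the close pairs summed 180 passed, of which 178 were among the 619, and all 619 kept their sign. Without axenic 8 h replicate 2 or 3, 298 and 320 passed, and without replicate 1 of every group 1499 did. The share higher was 61.6%, and 75.7% without composition scaling.

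At 13 h the adjacent genes were again among the largest rises in coculture, and an antifungal gene (CDS 1798) was among the largest falls. The GTP-binding protein (CDS 301) had a log2 fold change of 10.93 (SE 0.94, adjusted p = 2.47e-05), from 4.24 ± 1.84 to 8155 ± 1582 CPM (mean ± SD, n = 3). Formaldehyde dehydrogenase (CDS 302) rose by 9.67, the RDD family protein (CDS 303) by 7.39 and type B L31 (CDS 2803) by 6.67. S14 (CDS 838) was 217.2 times higher, with a counting interval of 59.7 to 1799.0. All 4 genes for bacillomycin D, an antifungal lipopeptide of the iturin family, fell. Their peptide synthetase genes CDS 1797 and CDS 1796 had log2 fold changes of -5.52 (SE 0.71) and -5.27 (SE 0.55), the synthetase CDS 1795 went from 850 ± 391 to 47.8 ± 10.7 CPM, and the malonyltransferase CDS 1798 had -6.79 (SE 0.74). The list passed (adjusted p = 0.000789), with adjusted p = 0.362 with an estimated correlation.

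Some genes of other antibiotic clusters fell at 13 h, though their lists did not pass. All 5 bacilysin genes fell, BacA (CDS 3515) by 3.81 on the log2 scale, and the adjacent MFS transporter (CDS 3516) had -6.62 (SE 0.56). Of 5 fengycin genes 3 fell, for example CDS 1822 (-1.84, SE 0.38), and of 15 difficidin genes 8 fell, with the cytochrome P450 (CDS 2200) at -1.80. Of 12 bacillaene genes 3 fell. These 4 lists had adjusted p = 0.122, 0.122, 0.0753 and 0.346. With the close pairs summed the 4 bacillomycin D genes passed, and 1 bacilysin, 1 difficidin and no fengycin or bacillaene gene did. The bacillibactin genes, for an iron-chelating siderophore, all rose (4 of 4, and 1 with the close pairs summed), among them the isochorismatase (CDS 2916, 3.11) and the dihydroxybenzoate dehydrogenase (CDS 2919, 2.92). Their list had adjusted p = 0.0274, and adjusted p = 0.362 with an estimated correlation.

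Genes for using plant and other polysaccharides were lower at 13 h. All 4 genes of the extracellular polysaccharide hydrolase list fell. Chitosanase (CDS 2991) fell by 3.62, pectate lyase (CDS 3655) by 3.57 and endo-1,4-beta-xylanase (CDS 3402) by 3.28 on the log2 scale. The list's other member, a chitin-binding protein (CDS 1737) that is not described as a hydrolase, had -2.74. The list passed (adjusted p = 0.000809), with adjusted p = 0.362 with an estimated correlation, and all 4 passed with the close pairs summed. Of 11 genes matched to alternative carbon use 9 fell and none rose. Examples were the GntP family permease (CDS 1802, -5.57), which matched by text alone, and the trehalose transporter (CDS 734, -4.50). That list had adjusted p = 0.0114, and adjusted p = 0.439 with an estimated correlation. Of 11 genes matched to nitrogen limitation 7 fell and 1 rose, with adjusted p = 0.0552 for the list. Examples were PgsB (CDS 3320, -7.04, which makes the polymer and is no nitrogen regulator) and urease beta (CDS 3405, -2.81). Trimmed of members that matched by text alone, among them PgsB, the nitrogen limitation list held 6. PgsC (CDS 3319) and CDS 3318 had -6.98 and -7.34. Gamma-glutamyltransferase (CDS 1833) had -7.47 (SE 0.78), from 904 ± 493 to 4.62 ± 4.15 CPM. The stress protein YvgO (CDS 2421) had -7.49 (SE 0.56) and the VWA domain protein (CDS 3413) -7.50 (SE 1.19). Of 9 histidine and tryptophan genes 6 fell, with anthranilate synthase component I (CDS 2086) at -5.03 (list adjusted p = 0.0753).

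Genes of 1 cytochrome d oxidase and of nitrate reductase were among the large rises at 13 h. Cytochrome d oxidase subunit II (CDS 3624) rose by 7.45 (SE 0.71) from 2.99 ± 0.170 to 534 ± 259 CPM, subunit I (CDS 3625) by 7.41 and the exporter CydD (CDS 3623), needed to assemble that oxidase, by 5.45. The second such oxidase did not pass (CDS 2804, -0.06 and CDS 2805, 0.94). Of the 26 genes of the respiration list, however, 15 fell and 5 rose (adjusted p = 0.346), and its members include cytochrome P450 genes that serve biosynthesis. Nitrate reductase alpha and beta (CDS 3466 and CDS 3465) rose by 6.43 (SE 0.66) and 4.28 (SE 0.51), and the nitrate transporter NarK (CDS 3470) by 2.83. In that list 4 of 9 rose, the median was -0.27 and the mean 1.22, and the test for a rise did not pass (adjusted p = 0.0753). L-lactate dehydrogenase (CDS 275) rose by 4.40. 4-aminobutyrate transaminase (CDS 357) rose by 6.43 (SE 0.88), with 1628 ± 1538 CPM in coculture. Of the 10 SigB list genes 6 rose and none fell, for example CDS 2235 (3.51), CDS 1873 (3.19) and SigB (CDS 450, 2.69, SE 0.26). The list had adjusted p = 0.000789, and adjusted p = 0.362 with an estimated correlation. Ribosomal protein genes were shifted up (7 of 49 rose, 1 fell, median 0.42, adjusted p = 0.0038), with adjusted p = 0.663 with an estimated correlation and adjusted p = 0.118 with fry. Of them L25/Ctc (CDS 53), which also belongs to the general stress list, rose by 2.44. Adjusted over the list alone 3 rose and none fell. Of 10 motility genes 6 rose and 1 fell, for example chemotaxis receptor CDS 1333 (3.89) and CDS 694 (2.80). The sporulation sigma factor SigF (CDS 2159) had -2.84 (SE 0.45), and of 34 genes matched to sporulation 12 fell and 3 rose (adjusted p = 0.459), a list that also took in an AbrB/SpoVT regulator and a TauE/SafE permease by their descriptions. Summing the close pairs left 6 alternative carbon, 6 nitrogen limitation, 5 histidine and tryptophan, 3 nitrate and 3 SigB list genes past the threshold in these directions. It also left 2 rising ribosomal protein genes, 1 rising motility gene, 5 falling sporulation genes and, of the respiration list, 5 rising and 9 falling genes.

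At 13 h, 1142 CDS passed, 454 higher and 688 lower in coculture. Of the 1549 described genes tested 775 passed in either direction, and the list counts at 13 h are to be read against that share. With the close pairs summed 405 passed, 399 of them among the 1142, and without replicate 1 of every group 2012 did. The share higher was 39.8%.

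**Figure D2:**
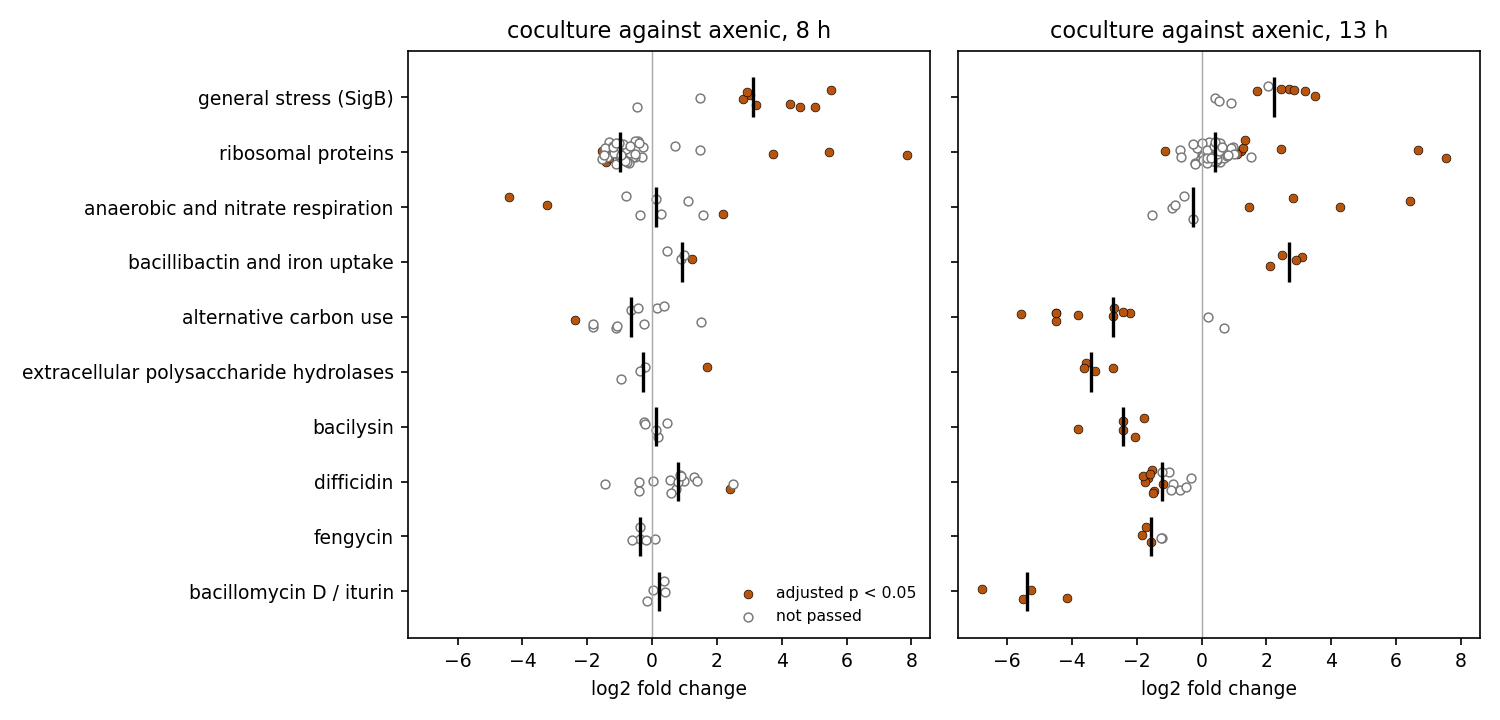
Log2 fold change of each tested member (points) of 10 gene lists in coculture against axenic culture at 8 h (left) and 13 h (right). Filled points had adjusted p under 0.05 and vertical bars are list medians, which for bacillomycin D were 0.20 at 8 h and -5.40 at 13 h, and for general stress 3.12 and 2.24.

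The coculture effects at 8 h and 13 h, which share no library, were related across genes (Pearson r = 0.34, Spearman rho = 0.22 over 3197 CDS, which are not independent replicates). Of the genes higher in coculture, 150 were called at both times, where 54.1 would be shared by independent lists, and of those lower 44 were, against 51.2. Another 33 were higher at 8 h and lower at 13 h (82.0 for independent lists), and 19 the reverse (33.8).

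The test of the difference between the 2 effects passed for 708 CDS, 240 with a more positive effect at 13 h and 468 with a more negative one. Of the 1549 described genes tested 414 passed it. The largest negative differences were in YvgO (CDS 2421, -8.03, SE 0.87, adjusted p = 0.000495) and in the adjacent genes for carbamoyl phosphate synthase small subunit (CDS 1056, -7.60, SE 2.04) and acetylornithine transaminase (CDS 1055, -7.18, SE 1.94). Next were the permease CDS 1802 (-7.09) and CoA transferase subunit B (CDS 1800, -6.94), adjacent to the biotin and bacillomycin D genes in CDS order. The largest positive ones were the hexulose phosphate genes (CDS 309, 5.54 and CDS 308, 5.30), whose coculture effect was less negative at 13 h, the ammonium transporter (CDS 3390, 5.17), 4-aminobutyrate transaminase (CDS 357, 4.91) and nitrate reductase alpha (CDS 3466, 4.23). For CDS 309 the axenic mean itself was low at 13 h, 8.8 CPM against 1636 at 8 h. Its coculture means were 11.6 CPM at 8 h and 2.9 at 13 h.

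By list, the difference was negative for bacillomycin D (3 of 4 genes, median -5.34, adjusted p = 0.000611), the hydrolases (4 of 4, median -3.16, adjusted p = 0.000611) and difficidin (8 of 15, median -2.30, adjusted p = 0.0113). With an estimated correlation these lists had adjusted p = 0.355, adjusted p = 0.355 and adjusted p = 0.747. Examples were the synthetases CDS 1797 (-5.56) and CDS 1796 (-5.12), the chitin-binding protein (CDS 1737, -4.42) and the difficidin P450 (CDS 2200, -4.21). It was positive for ribosomal proteins (10 of 49, median 1.22, adjusted p = 2.55e-10), for example S19 (CDS 121, 2.66) and L22 (CDS 122, 2.65), and for anaerobic and nitrate genes (4 of 9, median 1.70, adjusted p = 0.0213). With an estimated correlation they had adjusted p = 0.682 and adjusted p = 0.355. With the close pairs summed 60 CDS passed, all of them among the 708. They held 2 bacillomycin D genes, 1 gene of the hydrolase list, 1 difficidin gene and no ribosomal protein or nitrate gene. Without axenic 8 h replicate 2 or 3, 413 and 445 passed, without coculture 13 h replicate 2 or 3, 403 and 426, and without replicate 1 of every group 1684. The share with a more positive effect was 33.9%, and 20.8% without composition scaling.

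In axenic culture, biotin genes and 5 antibiotic clusters were higher at 13 h than at 8 h, and ribosomal protein genes lower. Biotin synthesis genes went from a few counts to high levels: 8-amino-7-oxononanoate synthase (CDS 1806) rose by 11.02 (SE 0.75, adjusted p = 1.7e-06) and the P450 of the same run (CDS 1803) by 11.19. The transaminase of that pathway (CDS 1807) was 3863.2 times higher, with a counting interval of 1321.7 to 18735.0, and BioD (CDS 1805) 1697.8 times, with 580.7 to 8234.8. 6-carboxyhexanoate-CoA ligase (CDS 1808) rose by 10.61. The bacillomycin D malonyltransferase (CDS 1798) was 2560.9 times higher, with an interval of 459.3 to 101175.5. Members of every list come from the authors' lists of changed genes, and 1192 of the 1549 described genes tested passed in this comparison, in either direction. Counts of members that rose or fell here are to be read against that share. Those of each other comparison are to be read against the share of described genes that passed in it. Every tested member of the bacillomycin D (4), fengycin (5), bacilysin (5), difficidin (15) and bacillaene (12) lists rose, with list medians of 6.63, 3.87, 5.40, 6.05 and 2.86. Examples were the bacillomycin D synthetase CDS 1797 (7.23), the fengycin synthetase CDS 1825 (5.40), and difficidin CDS 2200 (7.19) and CDS 2206 (6.82). Their list tests gave adjusted p = 0.00699, 0.0122, 0.0513, 1.43e-07 and 0.0481, and adjusted p = 0.434, adjusted p = 0.434, adjusted p = 0.532, adjusted p = 0.434 and adjusted p = 0.618 with an estimated correlation. Surfactin SrfAD (CDS 314, -0.31) did not pass, and of 4 bacillibactin genes 1 rose (adjusted p = 0.733).

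All 10 TCA cycle genes rose, such as citrate synthase (CDS 2647, 4.18) and aconitase (CDS 1762), as did all 9 histidine and tryptophan genes (CDS 2086, 5.62). All 4 genes of the polysaccharide hydrolase list rose too, among them the chitin-binding protein (CDS 1737, 5.56). Of 26 respiration genes 17 rose and 1 fell, for example cytochrome c oxidase subunit I (CDS 1442, 5.99). Adjusted p was 0.00358, 0.00274, 0.00699 and 0.0075 for these 4 lists, and adjusted p = 0.434 for each with an estimated correlation. The nitrogen limitation (8 of 11 rose, 2 fell), phosphate starvation (5 of 5 rose) and alternative carbon (7 of 11 rose, 2 fell) lists did not pass (adjusted p = 0.224, adjusted p = 0.123 and adjusted p = 0.304). Argininosuccinate synthase and lyase (CDS 2671 and CDS 2670) rose by 7.43 and 7.15. Of 34 sporulation genes 18 rose and 11 fell (adjusted p = 0.993), with SigF (CDS 2159) at 6.05 (SE 0.56) and a SafA/ExsA spore coat protein (CDS 2519) at 6.50. Of 49 ribosomal protein genes 44 fell and 1 rose, for example L4 (CDS 118, -2.82) and S19 (CDS 121, -2.70). That list had adjusted p = 4.58e-10, and adjusted p = 0.434 with an estimated correlation. Of 17 prophage and mobile element genes 10 fell (CDS 1198, the terminase large subunit, by 2.15 on the log2 scale). The list had adjusted p = 0.00481, and adjusted p = 0.434 with an estimated correlation. Other falls were the hexulose phosphate genes (CDS 309, -7.57 and CDS 308, -5.71), an MFS transporter and an aldo/keto reductase side by side (CDS 2637, -5.92 and CDS 2638, -5.73), an alpha-ketoacid dehydrogenase (CDS 1409, -4.74) and a nucleoside transporter (CDS 3637, -4.67). The list meant for stable RNA matched 5 rRNA-modifying enzymes instead, which all fell (adjusted p = 0.0345). It had adjusted p = 0.434 with an estimated correlation, and says nothing of RNA quality. Summing the close pairs left 8 bacillaene genes, 15 rising respiration genes, 14 rising and 7 falling sporulation genes, 42 falling ribosomal protein genes, 7 falling prophage genes and 4 of the rRNA-modifying enzymes past the threshold. In all 1769 CDS passed, 965 higher and 804 lower at 13 h, but 1082 and 611 without composition scaling and 912 and 939 with upper-quartile scaling, so their balance is not settled. The count was 1174 with the close pairs summed, of which 1161 were among the 1769.

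**Figure D3:**
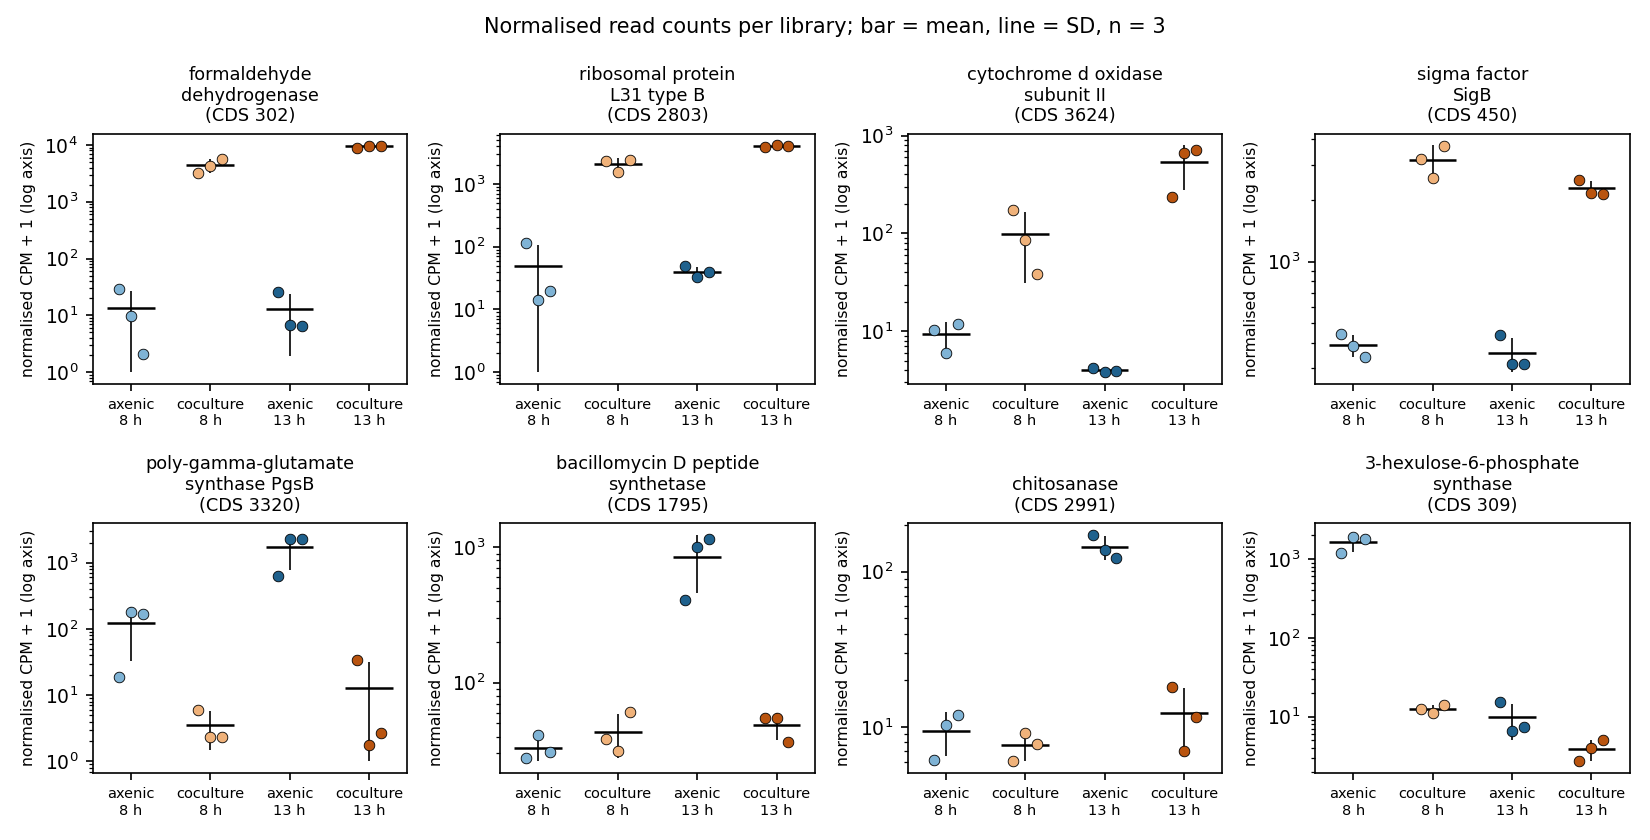
Normalised read counts (CPM plus 1, log axis) of 8 genes in each library, by group, with points for libraries, horizontal bars for means and vertical lines for SD (n = 3, not drawn below the axis value of 1). The formaldehyde dehydrogenase (CDS 302) was at 3209.3 CPM or more in every coculture library and at 27.8 or less in every axenic one, while the bacillomycin D synthetase (CDS 1795) was high in axenic culture at 13 h alone, at 407.0 CPM or more against 59.9 or less elsewhere.

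In coculture, the change from 8 h to 13 h covered fewer genes. The biotin genes rose here too: BioD (CDS 1805) was 1291.1 times higher (counting interval 357.1 to 10667.1), CDS 1808 was 1846.7 times higher (510.8 to 15254.2), and CDS 1807, biotin synthase (CDS 1804) and CDS 1803 rose by 10.13, 9.46 and 8.87. L-aspartate oxidase (CDS 2522), the entry step of NAD synthesis, rose by 9.25 (SE 0.98) to 2777 ± 83.5 CPM, against 551 ± 435 CPM in axenic culture at 13 h. All 15 difficidin genes rose (CDS 2211, 5.30 and CDS 2208, 5.09), all 5 fengycin genes (CDS 1825, 4.09), all 5 bacilysin genes, 6 of 12 bacillaene genes and all 10 TCA cycle genes (CDS 895, 3.33), and 7 of 9 histidine and tryptophan genes (CDS 2082, 3.66). The difficidin, fengycin, TCA cycle and histidine and tryptophan lists had adjusted p = 1.39e-10, 0.00379, 4.83e-05 and 0.000765. With an estimated correlation they had adjusted p = 0.449, adjusted p = 0.502, adjusted p = 0.449 and adjusted p = 0.2. The bacillaene list had adjusted p = 0.00923, and adjusted p = 0.615 with an estimated correlation. The bacilysin list did not pass (adjusted p = 0.0644). Of 4 bacillomycin D genes 1 rose (median 1.29, adjusted p = 0.454), and none of the 4 genes of the polysaccharide hydrolase list did, or 2 when adjusted over the list alone. Of 17 prophage genes 13 fell and 3 rose (median -2.54, adjusted p = 2.27e-10), with adjusted p = 0.332 with an estimated correlation. The terminase (CDS 1198) had -3.42 (SE 0.35) and XkdX (CDS 1221) was 46.6 times lower (counting interval 8.0 to 1878.3). The risers were LrgA/LrgB/CidA-type holin-like proteins, which are not phage genes.

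Further falls in coculture were a beta-ketoacyl synthase (CDS 537, -4.54), a LamB/YcsF protein (CDS 371, -4.10), acetoacetate decarboxylase (CDS 3018, -3.72), 2-dehydropantoate 2-reductase (CDS 3019, -3.63), a formate/nitrite transporter (CDS 2459, -3.72) and formate dehydrogenase alpha (CDS 2461, -3.50). The spore coat protein CDS 2519 rose by 8.60 and the adjacent sporulation protein CDS 2518 by 5.31, and SigF (CDS 2159) by 1.72 (SE 0.46). Of 34 sporulation genes 6 rose and 7 fell. Of 4 bacillibactin genes 3 rose (CDS 2915, 3.59). Ribosomal protein genes were shifted down (adjusted p = 0.00297, median -0.55, 3 of 49 fell), with adjusted p = 0.634 with an estimated correlation and adjusted p = 0.156 with fry. None of them fell when adjusted over the list alone. Summing the close pairs left no bacillomycin D or ribosomal protein gene, 4 bacilysin, 7 TCA cycle and 6 histidine and tryptophan genes, 13 falling and 1 rising prophage gene, and 4 rising and 2 falling sporulation genes past the threshold. In all 549 CDS passed, 330 higher and 219 lower at 13 h. Of the 1549 described genes tested 485 passed in either direction. With the close pairs summed 267 passed, 265 of them among the 549, without coculture 13 h replicate 1 332 did, and without replicate 1 of every group 1115. Of genes that rose with time, 279 were called in both cultures, against 99.6 for independent lists, and of those that fell 122, against 55.1. The time effects of the 2 cultures, which share no library, had r = 0.64 and rho = 0.56 across genes.

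Averaged over both times, 526 CDS were higher and 547 lower in coculture (562 and 482 without composition scaling), 1073 in all. After summing the close pairs 256 were higher and 194 lower, 450 in all. Of the SigB list 9 of 10 rose (median 2.85, adjusted p = 5.47e-07), with adjusted p = 0.578 with an estimated correlation. In that comparison 708 of the 1549 described genes tested passed in either direction. Averaged over both cultures, 880 CDS were higher and 839 lower at 13 h (823 and 983 with upper-quartile scaling), 1719 in all, and 1229 with the close pairs summed. The authors' deposited table for coculture lists 461 genes, 256 higher and 205 lower, and their table for time 1225, 701 higher and 524 lower. Of the 444 genes of the authors' deposited table for coculture that were tested here, 440 passed in the averaged comparison with the same sign, where 149.0 would fall among the 1073 by chance. Of 1189 genes of the authors' deposited table for time, 1188 did, against 639.3. These are the same libraries, so the counts compare analyses and not experiments. In the authors' deposited table for coculture formaldehyde dehydrogenase (CDS 302) has a log2 fold change of 9.16 and PgsB (CDS 3320) one of -6.90.

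The scale of these values rests on the assumption that most genes did not change. Without composition scaling the median of all genes moved by 0.17 for coculture at 8 h, 0.22 for time in axenic culture, 0.11 for time averaged and -0.23 for the difference of effects, and with upper-quartile scaling by -0.13 for time in axenic culture. The changes named above are relative to the TMM scale, and of 159 gene values checked, by comparison, none changed its call under either of these scalings. The 4 lists for macrolactin, purine synthesis, branched-chain amino acid synthesis and extracellular proteases had no described member and were not analysed here, nor were regulators without a description such as Spo0A and ComK.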

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

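The effect of coculture differed between 8 h and 13 h for 708 genes, by the test of the difference itself (the effect at 13 h minus that at 8 h, on the log2 scale). Among 105 genes named in the text 51 passed this test, and 5 gene lists did. Of all 3197 tested genes 22.1% passed it. The named genes were picked mostly for large changes, some of them in this same test, so a higher share among them is built in. With an estimated correlation none of the 26 lists passed. With the close pairs summed 60 of the 708 genes passed, none of them in the ribosomal protein list or the anaerobic and nitrate list. The single differences below are those with the libraries kept separate. Groups of 3 libraries were not tested for outlying samples. All tests of explanations in this part were chosen after the results were seen.

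The 5 lists had median differences of -5.34 (bacillomycin D), -3.16 (polysaccharide hydrolases), -2.30 (difficidin), 1.22 (ribosomal proteins) and 1.70 (anaerobic and nitrate genes). In this order they had adjusted p = 0.355, adjusted p = 0.355, adjusted p = 0.747, adjusted p = 0.682 and adjusted p = 0.355 with an estimated correlation. Single differences were more negative at 13 h for bacillomycin D CDS 1795 (-4.53), CDS 1796 (-5.12) and CDS 1797 (-5.56), difficidin CDS 2198 (-4.06), CDS 2200 (-4.21) and CDS 2206 (-2.30), the biotin gene CDS 1806 (-3.31), and CDS 1800 (-6.94) and CDS 1802 (-7.09) beside them. So they were for genes of the hydrolase list, CDS 1737 (-4.42), CDS 2991 (-3.25), CDS 3402 (-3.07) and CDS 3655 (-2.61), and for amino acid and arginine genes CDS 1055 (-7.18), CDS 1056 (-7.60), CDS 2086 (-4.72), CDS 2670 (-5.94) and CDS 2671 (-6.26). Stress and sporulation genes in this direction were YvgO CDS 2421 (-8.03), CDS 387 (-3.31), GlsB CDS 3563 (-5.10), catalase CDS 3640 (-3.10) and SigF CDS 2159 (-4.32). Metabolic, transport and phage genes were CDS 734 (-3.41), CDS 1221 (-4.03), CDS 1442 (-3.47), CDS 1762 (-1.09), CDS 1833 (-6.61), CDS 2804 (-4.95), CDS 3018 (-2.90), CDS 3019 (-2.92), CDS 3405 (-3.35) and CDS 3516 (-5.03).

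More positive at 13 h were ribosomal proteins CDS 118 (2.24), CDS 121 (2.66) and CDS 122 (2.65), hexulose phosphate genes CDS 308 (5.30) and CDS 309 (5.54), and nitrogen and nitrate genes CDS 300 (3.52), CDS 3390 (5.17), CDS 3465 (2.70), CDS 3466 (4.23) and CDS 3470 (2.57). Others were cytochrome d genes CDS 3623 (2.86) and CDS 3624 (3.86), the GTP-binding protein CDS 301 (3.29), CDS 357 (4.91), CDS 1409 (4.01), CDS 2637 (3.23), CDS 2638 (2.63) and CDS 3637 (3.04).

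Other splits of the samples were counted for each comparison. For the following comparisons 1 of 100 splits, the real one, gave as many genes. These were the averaged coculture effect (1073 genes, highest of the other splits 249), the averaged time effect (1719 and 261) and the difference of effects (708 and 469). The splits shuffled all group labels over both times and both cultures. They argue against groups without any difference. They cannot exclude chance for a coculture effect at a given time, for a time effect in a given culture, or for the difference of effects. For the last, the shuffling also broke up the time and culture effects, so these splits do not test it. These splits treat 12 libraries as independent, which the close pairs may not be (1.78 against a counting noise of 1). With the close pairs summed, the real split again gave the most genes for the averaged coculture effect (450 genes, highest other 135) and the averaged time effect (1229 and 901). For the difference of effects (60 genes) 3 of 100 splits of the summed libraries gave as many, under the share of 0.05, but the highest gave 614. Why a split gave a count that many times the real one was not tested, and nothing is concluded on the difference of effects from either set of splits. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. There, fitted on the 6 libraries, the real split gave 541 genes for coculture at 8 h, 1067 for coculture at 13 h, 1715 for time in axenic culture and 469 for time in coculture, and the highest other gave 0 in each.

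Replicates 2 and 3 of 3 groups were nearly identical. A difference in depth is argued against, since at equal depth replicate 1 was still 19.19 times or more as far from them as they were from each other. Reads of 1 library divided and deposited as 2 are argued against, since chi-square per degree of freedom was 1.78 or more, above the value of 1 for counting noise. Whether 2 libraries came from 1 culture cannot be told apart from separate cultures, since no label gives the cultures, and at coculture 8 h the replicates lay apart (23.54). No biological explanation was tested.

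Bacillomycin D genes were low in coculture at 13 h. A delay that left every antibiotic cluster the same share of its axenic log2 rise is argued against. The bacillomycin D genes kept a median share of 0.19 (highest 0.34), while the lowest share was 0.59 for fengycin, 0.39 for difficidin and 0.41 for bacilysin. Bacillaene, with shares of 0.21 to 1.80, overlapped the bacillomycin D genes. The cluster was picked for its low values at 13 h, which also enter these shares. Reads assigned to fengycin genes instead are argued against, since the highest fengycin log2 fold change was -1.22, and depth is too, since after thinning to equal depth the median was -5.41 and all 4 genes passed. A delay need not leave equal shares to clusters of different onset, so a later onset of this cluster in a delayed culture stays open. An effect of the fungus on this cluster may exist, and is a hypothesis found and tested on the same data.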

How the results depend on the processing

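No named gene or list that passed changed sign under any alternative run for it, but the balance of higher and lower counts turned in 3 comparisons. Time in axenic culture went from 965 higher and 804 lower to 912 and 939 with upper-quartile scaling, and averaged time from 880 and 839 to 823 and 983. Averaged coculture went from 526 and 547 to 562 and 482 without composition scaling, and to 256 and 194 with near-identical libraries summed. No composition scaling, summed near-identical libraries, the first library of every group left out, and trimmed lists were chosen after the data were seen.

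Summing near-identical libraries, which leaves fewer samples, gave 180 genes for coculture at 8 h, 405 at 13 h, 450 averaged, 1174 for time in axenic culture, 267 in coculture and 60 for the difference of effects. The averaged time effect stayed within 1.5 times. Leaving out the first library of every group, which leaves the close pairs of 3 groups, gave 1499, 2012, 1944, 1115 (time in coculture) and 1684 (difference), the other time counts staying within 1.5 times. Adjusted p under 0.01, a stricter threshold by construction, gave 245, 681, 615, 263 (time in coculture) and 205 (difference).

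Leave-one-out counts ran from 298 to 676 (coculture at 8 h; 298 and 320 without axenic 8 h replicate 2 or 3), 332 to 620 (time in coculture; 332 without coculture 13 h replicate 1) and 403 to 799 (difference; 413 and 445 without axenic 8 h replicate 2 or 3, 403 and 426 without coculture 13 h replicate 2 or 3). Other gene counts stayed within 1.5 times. The numbers do not pair the libraries, and with a replicate block the counts were 589, 1101, 1007, 1718, 483, 1682 and 609, in the order of the comparisons.

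Lists passing fell to 0 in all 7 comparisons with an estimated correlation. With fry, which tests members against no change and not against other genes, 8, 20, 16, 21, 18, 22 and 17 passed. The ribosomal protein list passed camera but not fry for coculture at 8 h (adjusted p = 0.154), coculture at 13 h (0.118) and time in coculture (0.156). With the 24 trimmed lists 3, 7, 7, 8, 7, 11 and 5 passed, against 3, 6, 7, 11, 8, 12 and 5 of 26 in the main setting. Leave-one-out ranges were 5 to 13 (coculture at 13 h; 13 without coculture 13 h replicate 1), 1 to 9 (coculture averaged; 1 without coculture 8 h replicate 1 or 3, 2 without coculture 8 h replicate 2, 4 without axenic or coculture 13 h replicate 1) and 5 to 9 (difference; 9 without axenic 13 h replicate 1). The correlation of the coculture effects was 0.31 with DESeq2, 0.38 with limma-voom, 0.29 with no filter, 0.38 with only the groups compared, and 0.28 to 0.40 leave-one-out. The cause was not tested where none is given.

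Of named gene values under alternatives set beforehand 1375 were the same, 1 stronger and 19 weaker, leave-one-out 1052, 3 and 55, and under added ones 442, 3 and 32. Of these 32 weaker values 31 came with the near-identical libraries summed, out of 159. If each close pair is 1 culture, the summed calls are the ones to use. All overlaps with the authors' lists stayed within 1.5 times. Scaling to stable RNA was not run, since the table holds coding sequences. Thinning to the smallest library left 589, 1068, 998, 1680, 494, 1636 and 623 genes, in the order of the comparisons. In simulated data of this design 16.2% of 4-fold changes were recovered for the difference of effects, a share that does not part depth from other limits.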

Other observations

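All tests of explanations in this part were chosen after the results were seen. In coculture, 12 genes rose 16-fold or more at both times. Beside the formaldehyde dehydrogenase run (CDS 301, CDS 302, CDS 303 and a DUF2680 protein, CDS 304), S14 (CDS 838), type B L31 (CDS 2803) and cytochrome oxidase subunit I (CDS 3625), they were a zinc ABC transporter binding protein (CDS 257, 4.21 at 8 h and 5.06 at 13 h on the log2 scale), lactate utilization protein B (CDS 3148, 4.06 and 4.37), an (Fe-S)-binding protein next to it (CDS 3149, 4.13 and 4.59), and sugar transporters CDS 3312 (4.32 and 4.23) and CDS 3715 (4.88 and 4.10). Type B L31, a copy that needs no zinc, lies beside the cytochrome and metal transport genes CDS 2804 to CDS 2810.

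Fungal reads assigned to bacterial genes are argued against as the source of the set: the genes lie in 8 places, runs of adjacent ones counted once, and 75.0% of these had an adjacent gene outside the set that rose at 13 h. The 95th percentile of 10000 random sets was 50%, and the value was 21.1% for all tested genes. Counted by gene, with genes of the set also taken as neighbours, the share was 91.7% for the set and 71.4% for all genes that rose at 13 h. Single places stay open. For L31, reads taken from its copy (CDS 3446) are argued against, since the copy had a log2 fold change of -0.28 (SE 0.38) at 8 h, where the gain would need -2.55. At 13 h L31 gained 3955.2 CPM, more than the 787.6 CPM the copy held in axenic culture. An untested hypothesis is that less zinc or another metal ion was available to the bacteria in coculture. Of 5 other metal ABC transporter genes 4 rose at both times: CDS 258 (2.22 and 4.28), CDS 259 (1.88 and 3.92), CDS 2808 (4.34 and 3.24) and CDS 2809 (3.87 and 3.70). The permease CDS 2807 rose at 8 h (5.06) and did not pass at 13 h (1.16). A manganese transporter rose too (CDS 2810, 3.65 and 3.57). Of 2 divalent cation transporters CDS 409 rose (2.30 and 2.47) and CDS 372 fell (-3.38 and -2.61), and a manganese efflux pump (CDS 3433) passed at neither time (-0.80 and -0.47). All 5 metal ABC transporter genes lie within 10 CDS of a gene of the set, so their count cannot decide the hypothesis. It stays open, and no metal was measured.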
